A study of Escherichia coli str. K-12 substr. MG1655 with 32 samples.

How the data were processed

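ChIP-exo libraries of Escherichia coli K-12 MG1655 were made from strains with 8-myc-tagged NtrC or Nac (anti-myc) and from the untagged strain (anti-RpoN, anti-RpoD), each on 4 nitrogen sources with biological duplicates, 32 samples in 16 groups. Groups were taken from the sample titles and characteristics. Reads were aligned with Bowtie 1.0.0 and the build is named as ASM584v2, per the submitters' processing notes. The peak caller, its threshold, the normalization of the binding intensity, how the duplicates were combined and any background subtraction are not given in the sources used here.

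The authors deposited 1 table per factor, with a start, an end and a binding intensity under each nitrogen source for every site, per the file headers. The deposited binding intensity is a signal that was above 0 wherever given, and its unit is not given. Each column is the authors' value for a group, and no column held a single replicate, so no test between replicates could be made. Blank cells were read as not listed. The read depth of each sample is unknown, and the number of reads behind a value, and so its precision, could not be given. Exact Clopper-Pearson 95% binomial intervals on shares of sites cover counting error only.

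Site lists were compared within a factor by row, since each row holds 1 site under up to 4 sources. A site was placed at the lowest start and highest end over its sources. Intensity changes were log2 ratios of the deposited values without a pseudocount at sites listed under both sources, summarised by the median and interquartile range over sites. A McNemar test of listing and a sign-flip test of the ratios across sites were planned and computed, but their p-values are not reported, since sites are not replicates and each source has 1 value. Sites are named by rules fixed before the data were examined: the 10 strongest of each factor, the 5 largest rises and 5 largest falls against ammonia per factor and source, members of fixed lists near NtrC sites or at the strongest sites, and genes near sites of NtrC and also of RpoN or Nac. Further sites were chosen after their values were seen: the remaining NtrC sites, RpoD sites beside nupC and metal genes, those of the first stretch of the chromosome and those listed for several factors with nearly the same edges.

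Sites of different factors counted as together when at most 100 bp lay between their edges. The count was compared with 10000 circular shifts of the smaller set along a chromosome ending at the last deposited position, 4638732, and two-sided p-values were adjusted by Benjamini-Hochberg over the 6 pairs. Shares of site centres outside coding sequences were compared with 10000 circular shifts within the stretch used. The gene table held 4651 genes of ASM584v2, 4290 of them protein-coding, and no strand and no genome sequence was used here. For that reason the planned motif search was not run, and the planned rule for genes, a start codon within 300 bp of the site centre, was replaced by either gene end within 300 bp.

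As the positions past the first stretch did not meet the gene table as numbered, RpoD centres were divided into 3 stretches by dynamic programming, each with the offset of up to 3000 bp in either direction, in steps of 4 bp, that placed most centres outside coding sequences. No position was changed in the report, and deposited positions are printed throughout. Gene lists were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over lists and factors. The 13 lists were fixed before the data were examined: nitrogen scavenging (Ntr), other RpoN functions, pyrimidines and nucleosides, textbook Nac targets, glutamate and ammonia assimilation, polyamines with arginine and GABA, amino acid biosynthesis, heat shock, flagella and chemotaxis, central carbon metabolism, general stress, ribosomal proteins, and ribosomal and transfer RNA. All of their genes matched the table.

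Alternatives were the upper part of sites by intensity, merging of sites closer than 50 bp, centres within 20 bp, pseudocounts of 0.1 and 10, scaling of sources to the same median, sites sharing at least 1 bp or at most 200 bp apart, gene ends within 150 or 500 bp, a background of genes near RpoD or RpoN sites, and whole sites outside coding sequences. The whole chromosome at the fitted offsets was added after the data were seen. The procedures were tested on simulated data. With 10 of 23 sites planted beside 385 others, all 20 simulated tables passed, and none of 20 with nothing planted did. These sites were placed at random along the chromosome, so a shared preference for DNA outside coding sequences was not simulated. Offsets planted in 3 segments of 2632 simulated sites were recovered with an error of 0 bp, and all 20 planted gene lists drawn from 4651 genes passed. The lists were drawn at random, without the clustering of related genes along the chromosome. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.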

Results

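Binding of 4 DNA-binding proteins was mapped along the single chromosome of Escherichia coli K-12 MG1655 by ChIP-exo, in which immunoprecipitated DNA is trimmed by an exonuclease up to the bound protein, so that each site is narrow. NtrC is the response regulator that activates genes of nitrogen shortage. Nac is a LysR-type regulator whose own gene is an NtrC target. RpoN is the sigma factor that NtrC-activated promoters use, and RpoD is the housekeeping sigma factor. NtrC and Nac were precipitated through an 8-myc tag, and RpoN and RpoD through antibodies to the native proteins in the untagged strain. Cells were grown to mid-log phase at 37 °C on 0.2% glucose with ammonia, the preferred nitrogen source, or with 2 g/L glutamine, cytidine or cytosine. There were 32 samples in 16 groups, with 2 replicates of each factor and nitrogen source.

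The deposited tables gave 1 site list per factor and, for every site, 1 position and 1 binding intensity per nitrogen source. They held 23 NtrC sites, 530 Nac sites, 385 RpoN sites and 2632 RpoD sites, with median widths of 58, 34, 34 and 50 bp. Replicates were not given separately, so no value below has a spread between replicates, and spreads are those across sites. Read depth per sample is unknown. A site without an entry under a nitrogen source is called not listed there, which does not show that the protein was absent. The labels name M9 and W2 minimal media in a single text without pairing each with a nitrogen source, so a difference between base media cannot be separated from a difference between ammonia and the other sources.

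To ask where NtrC bound when ammonia was replaced, its 23 sites were compared between sources. All 23 were listed under glutamine, cytidine and cytosine, and 5 of them under ammonia. At those 5 sites every intensity was higher on the alternative sources, with median ratios to ammonia of 35.3-fold under glutamine, 36.9-fold under cytidine and 46.5-fold under cytosine. The strongest site, at positions 4056221 to 4056285, had intensities of 88.5 under ammonia, 2640 under glutamine, 3270 under cytidine and 4112 under cytosine. The next, at 847362 to 847408, had 13.5 under ammonia and 831, 1131 and 1484 in the same order. The widest change was at 688329 to 688411, where 0.98 under ammonia compared with 242 under glutamine, 239 under cytidine and 237 under cytosine, ratios of 247, 244 and 242. The site at 2424947 to 2425005 had 4.55 under ammonia and 160, 149.5 and 187 under the alternatives. The fifth, at 4054376 to 4054408, had the smallest ratios, 15.9, 13.8 and 15.2. No scale between sources is given, so the ratios are those of the values as deposited. Dividing each source by its median over these 5 sites centres the ratios by construction and tests no direction; the log2 ratios at 4054376 to 4054408 were then -1.13, -1.32 and -1.17.

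The 18 NtrC sites that were not listed under ammonia were weaker. Their median intensity was 12.9 under glutamine, 6.64 under cytidine and 8.54 under cytosine, against 242, 239 and 237 for the 5 listed ones. The 5 were also the strongest 5 of the 23 under glutamine and under cytosine. Under cytidine the site at 1863669 to 1863753, not listed under ammonia, reached 107.8 and displaced 1 of them. Between the alternative sources the NtrC sites differed far less than from ammonia. Cytidine was lower than glutamine at 17 of 23 sites, with a median log2 ratio of -0.40 (interquartile range -0.98 to -0.01), and cytosine was lower at 14 of 23, with a median of -0.11 (-0.44 to 0.23). The largest single drop was at 1073229 to 1073272, which had 22.5 under glutamine, 15.3 under cytidine and 5.95 under cytosine.

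**Figure D1:**
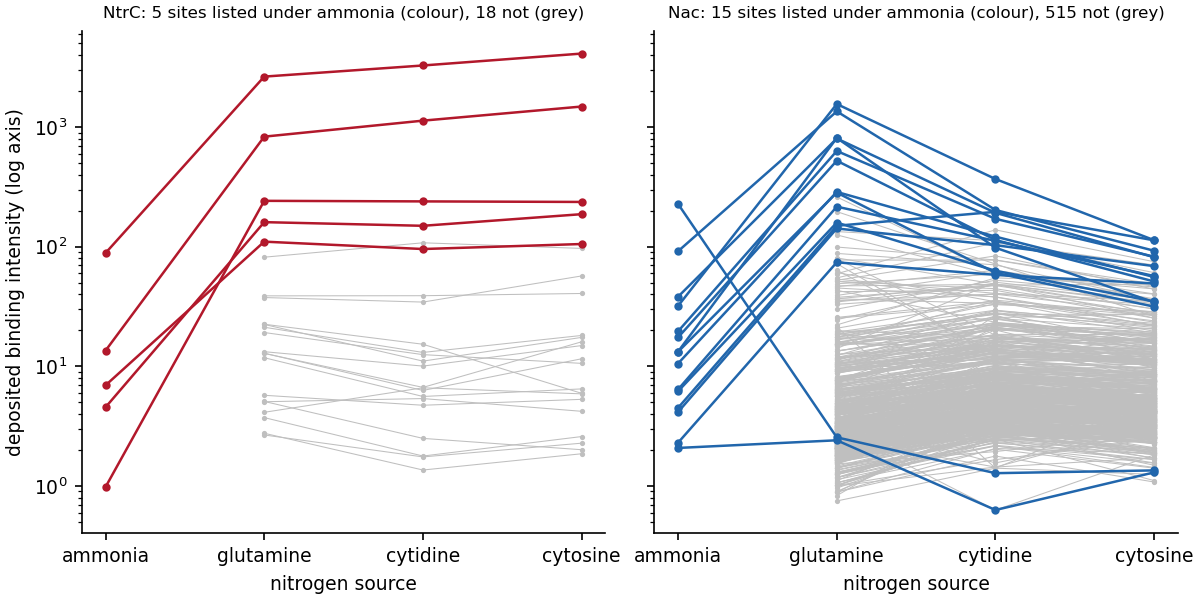
Deposited binding intensity (log axis, no unit given) of every NtrC site (left) and Nac site (right) under the 4 nitrogen sources, with 1 line per site; lines in colour are sites listed under ammonia and grey lines are the others. The strongest NtrC site climbs from 88.5 under ammonia to 4112 under cytosine, while the Nac site at 227.7 under ammonia falls to between 1.28 and 2.55.

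Nac showed the sharpest difference in the number of sites. Under ammonia 15 of its 530 sites were listed, 2.83% (exact 95% binomial interval 1.59 to 4.62%, which covers counting error only), against 522 under glutamine, 529 under cytidine and 529 under cytosine. All 15 were listed under every source, and 505 sites were listed under the 3 alternatives alone. At the 15 shared sites the median intensity ratio to ammonia was 30.0-fold under glutamine, 8.72-fold under cytidine and 3.54-fold under cytosine. Intensity was higher than under ammonia at 14 of the 15 sites under glutamine and at 13 under each of the other 2. The strongest Nac site, at 1402593 to 1402659, had 32.0 under ammonia, 1558 under glutamine, 368 under cytidine and 113 under cytosine. The site at 3925015 to 3925048 had 91.6, 1352, 203 and 92.5 in the same order, so that cytosine and ammonia gave nearly the same value there. At 3056478 to 3056511 the intensity under cytidine, 196, exceeded that under glutamine, 150, and the ratio to ammonia was 25.1 or higher under each alternative source. Scaling each source to the same median over the shared sites centres the ratios by construction and left median log2 ratios of 0.49, 0.04 and -0.25, so it tests no direction.

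A single Nac site ran strongly the other way. At 3889533 to 3889578 the intensity was 227.7 under ammonia, the highest of the 15 sites there, and 2.55 under glutamine, 1.28 under cytidine and 1.35 under cytosine. The log2 ratios to ammonia were -6.48, -7.47 and -7.40. The only other site with a lower value than under ammonia was at 2561401 to 2561446, with 2.08 under ammonia, 2.41 under glutamine, 0.63 under cytidine and 1.30 under cytosine.

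Among the alternative sources, most of the strongest Nac sites differed in direction from the set as a whole. Over the 521 sites listed under both, cytosine exceeded glutamine at 439, with a median log2 ratio of 0.49 (interquartile range 0.20 to 0.74), and cytidine exceeded glutamine at 477 of 521, with a median of 0.73 (0.51 to 0.94). Of the 15 strongest sites under cytosine, 12 had a lower value under cytosine than under glutamine and 11 a lower value under cytidine than under glutamine, as at 357914 to 357979, where glutamine gave 810, cytidine 98.0 and cytosine 34.3. The lowest cytosine to glutamine log2 ratio of any Nac site was -4.56. The 5 strongest sites held 44.7% of the summed Nac intensity under glutamine, 15.04% under cytidine and 9.29% under cytosine.

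RpoN bound many sites under every source. Of its 385 sites 312 were listed under ammonia, 380 under glutamine, 384 under cytidine and all 385 under cytosine, and 311 were listed under all 4. Intensity under the alternatives was higher than under ammonia at 298 of 312 sites for glutamine, 284 of 311 for cytidine and 299 of 312 for cytosine. The median ratios were 3.09-fold (interquartile range of the log2 ratio 1.18 to 1.91), 2.50-fold (0.80 to 1.73) and 2.20-fold (0.87 to 1.39). Whether the sources share a scale is not given in the sources used here, and scaling to the same median, which centres the ratios by construction (median log2 ratios of -0.02, -0.08 and 0.09), tests no direction.

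The largest RpoN ratios were at 2 overlapping sites under cytosine. The site at 1271637 to 1271667 had 7.93 under ammonia, 12.5 under glutamine, 29.5 under cytidine and 197 under cytosine, a 24.9-fold ratio to ammonia, and its neighbour at 1271613 to 1271645 had a 10.8-fold ratio under cytosine. Under glutamine the largest ratios were 7.48 at 1165229 to 1165259 and 7.14 at 361064 to 361097. The strongest RpoN site of all, at 2848614 to 2848649, changed little, with 1304 under ammonia, 1724 under glutamine, 1050 under cytidine and 2294 under cytosine. Next to strong NtrC sites, the RpoN site at 4056129 to 4056164 had 165 under ammonia and 303, 221 and 698 under the alternatives, and that at 688439 to 688474 had 91.3 and then 240, 159 and 483. Their ratios under cytosine, 4.23 and 5.29, lay above the RpoN median of 2.20, and the latter was among the 5 largest. Under glutamine their ratios, 1.84 and 2.63, lay below the RpoN median of 3.09. Under cytidine, 1.34 and 1.74 lay below the median of 2.50. At 2424857 to 2424892, beside another strong NtrC site, RpoN had 5.03 under ammonia and 17.9, 9.75 and 18.9 under the alternatives. There the glutamine ratio lay above the RpoN median. At 847270 to 847305, also beside a strong NtrC site, RpoN had 66.4 and then 169, 104 and 269. The lowest RpoN ratios were 0.38 under glutamine at 2561402 to 2561446 and 0.37 under cytidine at 3717903 to 3717933. The 73 RpoN sites not listed under ammonia had a median intensity of 3.36 under cytosine, against 9.94 for the 312 listed ones.

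RpoD sites were the most numerous and shifted the least as a whole, in the opposite direction. Of 2632 sites 2512 were listed under ammonia, 2323 under glutamine, 2577 under cytidine and 2592 under cytosine, and 2285 (86.8%) under all 4. Glutamine had the fewest, and 213 sites were listed under ammonia and not under glutamine, against 24 the other way. When sites listed under both with centres more than 20 bp apart were counted as separate, the 24 became 42, and the 213 rose by as many. Intensities were lower than under ammonia at 1949 of 2299 sites for glutamine, 1828 of 2465 for cytidine and 1526 of 2474 for cytosine. The median log2 ratios were -0.73, -0.45 and -0.21. Scaling to the same median, which centres the ratios by construction, left 0.01, -0.02 and -0.07 and tests no direction of the whole set.

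Against that small shift, single RpoD sites changed by up to 247-fold. The site at 2039357 to 2039409 had 0.2 under ammonia, 35.3 under glutamine, 34.8 under cytidine and 49.3 under cytosine. The site at 2008573 to 2008625 had 0.73 and then 24.1, 45.3 and 66.5, and the site at 312003 to 312052 had 0.43 and then 20.4, 9.96 and 28.1. These 3 sites were among the 5 largest rises for every alternative source, comparisons that share the ammonia value. Their ammonia values lay below the RpoD lower quartile under ammonia, 1.55, so the size of these ratios rests on low denominators of 1 value each. Values differed between the alternatives at 3453531 to 3453582, with 1.98 under ammonia, 3.89 under glutamine, 15.6 under cytidine and 69.1 under cytosine. The steepest fall was at 3955918 to 3955973, from 25.1 under ammonia to 1.2 under glutamine, a log2 ratio of -4.39, with 3.29 and 3.62 under cytidine and cytosine. At 3352514 to 3352565 the intensity was graded, with 158 under ammonia, 63.5 under glutamine, 24.2 under cytidine and 9.56 under cytosine. The strongest RpoD site, at 2729322 to 2729376, varied little, with 554, 488, 479 and 637.

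**Figure D2:**
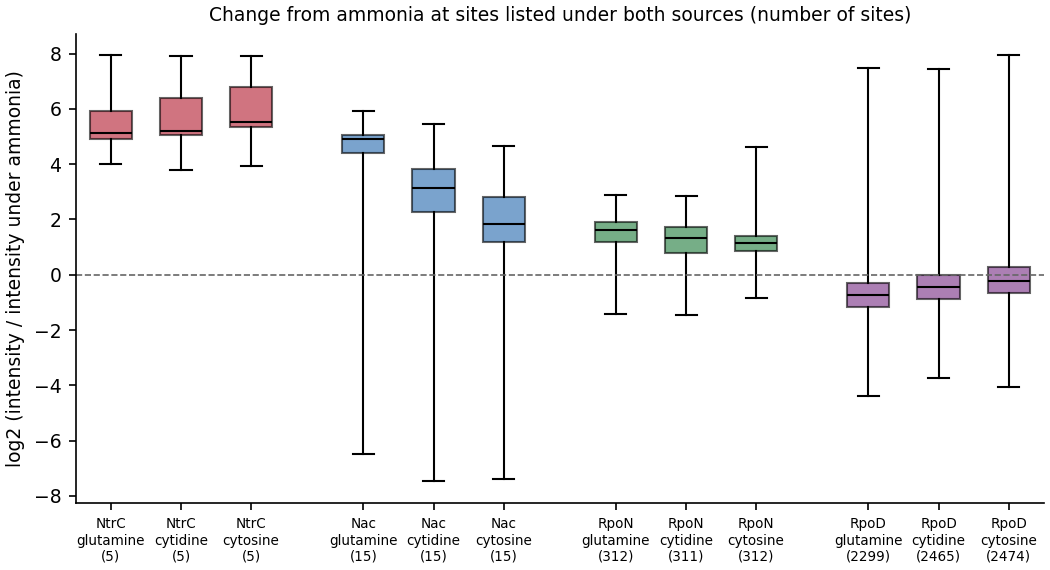
Log2 ratio of the deposited intensity under each alternative source to that under ammonia, at sites listed under both (number of sites in brackets); boxes span the interquartile range across sites, the line is the median and whiskers reach the lowest and highest site. NtrC medians lie between 5.14 and 5.54, RpoN medians between 1.14 and 1.63, and RpoD medians between -0.73 and -0.21.

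Of the 21 RpoD sites named for their rise or fall, 6 lay within 100 bp of a Nac site, as did 197 of all 2632 RpoD sites, and at 5 of these, all named for a fall, the sites of both proteins overlapped. They included the site at 3056458 to 3056510, where RpoD went from 39.15 under ammonia to 4.86 under cytosine beside the Nac site at 3056478 to 3056511, and the site at 3352514 to 3352565 beside the Nac site at 3352497 to 3352529. The remaining pair was the RpoD site at 2008573 to 2008625, named for a rise, and the Nac site that ended next to it at 2008572. Among all RpoD sites near a Nac site, those at least 2 log2 units from the median ratio lay mostly above it, with 9 above and 0 below under glutamine, 8 and 2 under cytidine and 16 and 6 under cytosine.

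Whether the factors shared sites was tested by counting sites of the smaller set within 100 bp of the larger set and comparing with 10000 circular shifts along the chromosome. NtrC and RpoN were the most closely linked, with 17 of 23 NtrC sites (73.9%, exact 95% interval 51.6 to 89.8%) near an RpoN site, against 0.54 ± 0.73 (SD) sites over the shifts (permutation p adjusted over 6 pairs = 0.0003, from a raw value of 0.0002 that is the smallest the shifts can give). Of the 5 NtrC sites listed under ammonia, 4 had an RpoN neighbour, and the site at 4054376 to 4054408 had none. NtrC and RpoD sites lay together at 14 of 23 NtrC sites against 3.49 ± 1.73 (permutation, adjusted p = 0.0003), but in the stronger sites of each set at 1 of 11, where the call ended (permutation p = 1). Nac and RpoD sites lay together at 161 of 530 Nac sites against 75.6 ± 7.93 (permutation, adjusted p = 0.0003). Circular shifts do not keep a preference for DNA outside coding sequences, where 72.5% of RpoD centres lay at the fitted offsets. For NtrC, Nac and RpoN the shares were 91.3%, 35.7% and 26.0%, against 14.2% of bases. The excesses with RpoD, here and below, therefore cannot be told apart from a shared placement between genes.

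RpoN and RpoD sites lay together at 97 of 385 RpoN sites against 55.0 ± 7.04 (permutation, adjusted p = 0.0003), and among the stronger sites at 20, where the excess did not pass (permutation p = 0.139). NtrC and Nac sites lay together at 3 of 23 NtrC sites against 0.76 ± 0.86 (permutation, adjusted p = 0.0786; with at least 1 bp shared, 2 sites and an unadjusted permutation p of 0.0418), and RpoN and Nac sites at 19 of 385 RpoN sites against 11.7 ± 3.39 (permutation, adjusted p = 0.0672). With at least 1 bp shared, 12 RpoN sites met a Nac site and the unadjusted permutation p was 0.0004. Of the 19 RpoN sites within 100 bp of a Nac site, 10 had both edges within 5 bp of the edges of the Nac site. These 10 are among the 12 with shared bases. The site at 2561401 to 2561446 was listed with nearly the same edges for NtrC, Nac and RpoN, as was the site at 2563311 to 2563355. They are the 2 NtrC sites that shared bases with a Nac site. Both p-values for shared bases therefore rest mostly on sites with nearly the same edges, whose origin is not settled.

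**Figure D3:**
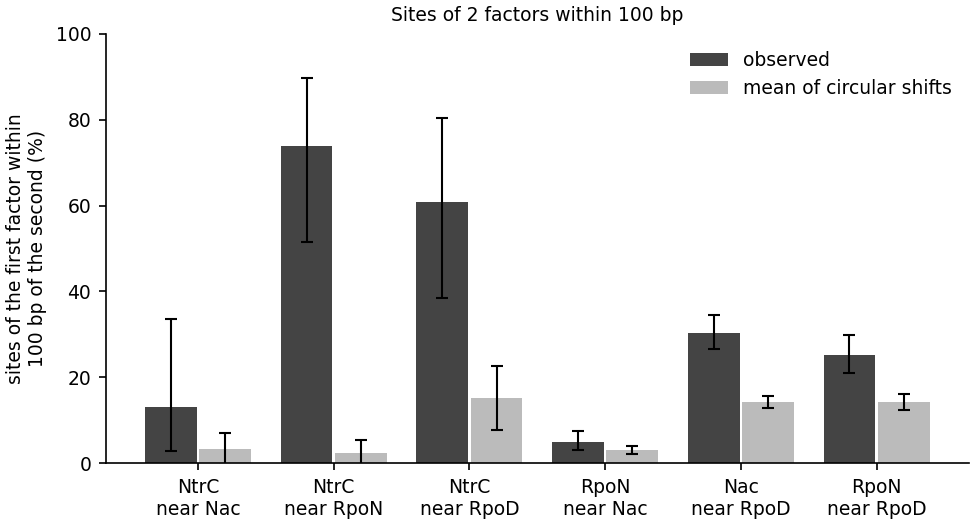
Share of sites of the first factor that lie within 100 bp of a site of the second, observed (dark bars, exact 95% binomial interval) and as the mean of 10000 circular shifts (light bars, SD of the shifts). NtrC near RpoN stands at 73.9% against 2.34% over the shifts.

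Site positions were set against the protein-coding genes of the ASM584v2 gene table, the build that the submitters' processing notes name. Up to RpoD centre 257812, 108 of 159 RpoD centres (67.9%, exact 95% interval 60.1 to 75.1%) lay outside coding sequences, against 12.8% ± 2.95 (SD) over circular shifts of this stretch (permutation, adjusted p = 0.0006). The end of the stretch was fitted to the placement of these same RpoD centres, a choice that the interval and the p-value do not cover. From there on the share was 12.99% of 616 sites up to 1293706 and 13.7% of 1857 sites up to 4638706, close to the 14.2% of bases that lie outside coding sequences. When a fixed number of bases was added to all centres of a stretch, the share peaked at 72.7% with 780 bp added in the middle stretch, the best value being tied from 772 to 780 bp, and at 72.9% with 1972 bp added in the last. In the first stretch 0 bp was among the best values. Gene names are therefore given as results for the first stretch only; elsewhere they appear at the fitted offsets, as hypotheses, after these results.

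**Figure D4:**
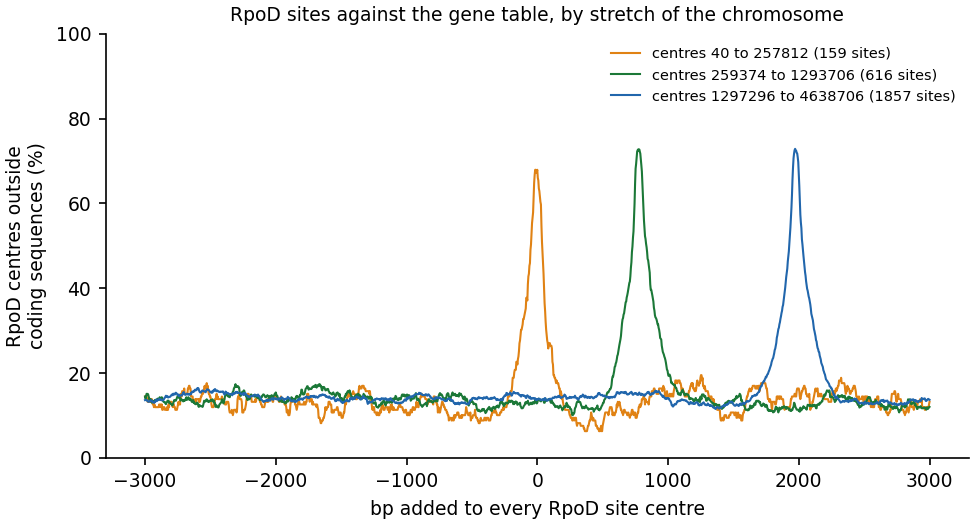
Share of RpoD site centres outside protein-coding sequences (vertical axis, percent) after adding the number of bases on the horizontal axis to every centre, for 3 stretches of the chromosome. Each stretch has 1 sharp peak, at 0, 780 and 1972 bp.

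Within the first stretch no NtrC site was listed, and the strongest Nac site lay between glnD, which encodes the uridylyltransferase of the nitrogen-sensing PII protein, and map, which encodes methionine aminopeptidase. At this site, 188653 to 188686, the intensity was 17.45 under ammonia, 523 under glutamine, 114 under cytidine and 51.2 under cytosine, and it was the only Nac site of the 26 in this stretch listed under ammonia. A further Nac site inside map, at 189226 to 189255, had 21.4 under glutamine and 1.41 under cytidine. The Nac sites inside the fimbrial genes htrE and yadV, at 154403 to 154436 and 155754 to 155787, showed the opposite order, with 18.6 and 15.4 under glutamine and 27.2 and 20.25 under cytidine. Of the 26 Nac centres 9 (34.6%) lay outside coding sequences, against 12.9% ± 6.76 over shifts (permutation, adjusted p = 0.0174). The 13 RpoN sites of this stretch lay inside genes at 12 positions, and 7.69% outside against 12.75% ± 9.65 over shifts did not pass (permutation, adjusted p = 1), with only 1 site outside. Over the whole chromosome at the fitted offsets, chosen after the data were seen, 26.0% of 385 RpoN centres lay outside, not tested against shifts. The strongest RpoN site of the first stretch was inside metQ, of methionine import, with 8.35 under ammonia and 36.3 under glutamine. The next was inside carB, a subunit of carbamoyl phosphate synthetase, with 15.6 and 35.4.

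RpoD sites of the first stretch included 2 between dapB and carA, the latter encoding the other subunit of carbamoyl phosphate synthetase, which serves pyrimidine and arginine synthesis. Both had lower values than under ammonia on cytidine and on cytosine. At 29527 to 29577 the intensity was 15.1 under ammonia, 1.14 under cytidine and 6.66 under cytosine, and at 29603 to 29652 it was 4.19, 0.61 and 1.05, while neither site was listed under glutamine. The log2 ratios of -3.73 and -2.78 under cytidine compare with the RpoD median of -0.45. By their highest value over the sources, the 2 strongest RpoD sites of the stretch lay beside rpsT, which encodes a ribosomal protein, with 83.2 under ammonia and 114 under cytosine, and between gmhB and the ribosomal RNA gene rrsH, with 80.0 and 112. Between yjtD and thrL, the leader of the threonine operon, the intensity at 125 to 175 was 84.15 under ammonia, 49.8 under glutamine, 68.9 under cytidine and 106 under cytosine. Between dnaQ and aspV, a tRNA gene, at 236882 to 236940, it was lower than under ammonia on each alternative, with 89.7 against 25.9, 34.0 and 29.35. Near leuL, the leader of the leucine operon, RpoD sites at 83714 to 83763 had 103 and 104 under ammonia and cytosine, and an RpoN site listed at 83710 to 83738 had 2.65 and 1.99.

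Of the 13 fixed gene lists 9 were tested in the first stretch, for Nac, RpoN and RpoD, and no pair of list and factor passed. With a gene counted as near a site when either of its ends lay within 300 bp of the centre, these pairs had an adjusted p of 1 by Fisher's exact test over 251 genes. The closest was the depletion of rRNA and tRNA genes near RpoD sites, with 2 of 7 genes against 4.74 expected (Fisher's exact p = 0.0373 before adjustment). The nitrogen scavenging list had 1 gene in this stretch, glnD, and the pyrimidine list 3, of which carB lay near a Nac site of intensity 0.89 under glutamine and 2.06 under cytidine. With so few members, a p that misses the threshold says little here.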

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

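The whole chromosome at the fitted offsets was an alternative chosen after seeing the data, and all others were written before. Each column is 1 value per nitrogen source, so leaving out a replicate and a replicate block were not run. No paired analysis was possible because the tables hold 1 value per nitrogen source and not 1 per replicate. Read depth per sample is unknown, so what depth limits was not measured, and the exact intervals cover counting error only. Not run were the motif tests with their alternatives, random intergenic positions and transcription units, and each gene end stood in for a start codon.

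With the upper part of sites by intensity, which keeps fewer sites by construction, NtrC had 11 sites listed under each alternative source, Nac 262, 263 and 263 (glutamine, cytidine, cytosine), RpoN 185, 192, 192 and 192 and RpoD 1288, 1274, 1306 and 1310 (ammonia first). Sites listed under the source and not under ammonia numbered 6, 6 and 6 for NtrC, 248, 249 and 249 for Nac, 7, 7 and 7 for RpoN and 7, 24 and 25 for RpoD. Overlaps were 0 for NtrC with Nac, 8 for NtrC with RpoN, 1 for NtrC with RpoD, 4 for RpoN with Nac, 58 for Nac with RpoD and 20 for RpoN with RpoD. In the first stretch 0% of RpoN and 80.2% of RpoD centres lay outside coding sequences.

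Asking for at least 1 bp shared gave overlaps of 2 for NtrC with Nac (unadjusted permutation p = 0.0418, against 0.0786 before), 7 for NtrC with RpoN, 8 for NtrC with RpoD, 12 for RpoN with Nac, 73 for Nac with RpoD and 49 for RpoN with RpoD. With centres within 20 bp required for a match, 42 RpoD sites counted as unmatched under glutamine, against 24 listed there and not under ammonia. The added sites were listed under both sources and were added to the ammonia side as well. With whole sites outside coding sequences the RpoD share was 48.4%, against 67.9%. At the fitted offsets 5 pairs of list and factor passed, against 0. Of these, ribosomal and transfer RNA genes near Nac sites did not pass Fisher's exact test with gene ends within 150 bp (adjusted p = 0.121) or 500 bp (adjusted p = 0.191), and passed with genes near RpoD or RpoN sites as background (adjusted p = 0.0122). Within 500 bp, general stress (adjusted p = 0.0312) and nitrogen scavenging genes (adjusted p = 0.0358) near RpoD sites passed Fisher's exact test, and with genes near RpoD or RpoN sites as background the textbook Nac targets did (adjusted p = 0.044).

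Scaling each source to the same median removes a common shift by construction. The median log2 ratios became 0.49, 0.044 and -0.25 for Nac, -0.022 (glutamine) and -0.084 (cytidine) for RpoN, and 0.011 (glutamine) and -0.068 (cytosine) for RpoD. At single NtrC sites they became -1.13, -1.32 and -1.17 at 4054376, -0.22 under glutamine at 4056221 and -0.069 under cytidine at 2424947. A pseudocount of 10 gave a Nac cytosine median of 1.47, against 1.83, and the upper part by mean intensity an RpoD cytosine median of -0.17, against -0.21; the cause was not tested. Merging sites closer than 50 bp left all 16 counts within 1.5 times, a gap of 200 bp changed no call among 6 pairs, and a pseudocount of 0.1 left 12 medians in the same direction.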

Other observations

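The tests below were chosen after the result was seen, except the 2 tests on metal genes, which were written before their values were seen. Gene names past the first stretch rest on the fitted offsets and are hypotheses. With them, the strongest NtrC site (4056221 to 4056285, 4112 under cytosine) lies beside glnA, encoding glutamine synthetase, and those at 847362 to 847408 and 2424947 to 2425005 (1131 and 149.5 under cytidine) lie beside glnH, of glutamine import, and hisJ and argT, of histidine and arginine import. Weaker ones lie beside glnK (471646), nac (2060086), astC (1830282), rutA (1073229), ddpX (1561223) and yeaG (1864792). In all 14 of the 23 NtrC sites lie beside a gene of the nitrogen scavenging list and 9 do not. Among the 9 are the site with the widest change (688329, between insH3 and lnt), 1863669 (between yeaE and mipA), 2912481 (inside rlmD) and 1906198 (nearest yebO). Beside means a gene end within 300 bp of the site centre, so a list gene farther off is not counted. At 2912481 the neighbouring genes relA and barA lie 835 and 571 bp away, outside this window. The split therefore does not show that the 9 sites have no target on the list. Of the 53 genes of the nitrogen scavenging list 16 lay near an NtrC site against 0.49 expected (Fisher's exact test, adjusted p = 7.47e-20). Near an RpoN site lay 16 against 4.70 (Fisher's exact test, adjusted p = 9.61e-05). Fisher's exact test counts genes as independent, although 1 site can lie near several list genes, as with hisJ and argT at 2424947. Its p-values for these lists can therefore be too small, and other offsets gave up to 14 nitrogen scavenging genes beside NtrC sites (below). Of 58 genes of other RpoN functions 22 lay near an RpoN site against 5.14 (Fisher's exact test, adjusted p = 2.93e-08), among them rpoH (site at 3598836 to 3598871) with 217 under ammonia and 444 under glutamine, and 20 near an RpoD site against 36.8 (adjusted p = 9.61e-05). The textbook Nac targets had 7 of 19 genes near a Nac site against 2.82 and glutamate and ammonia assimilation 7 of 20 against 2.97, both with an adjusted p of 0.0872. Against a background of genes near RpoD or RpoN sites the textbook Nac targets passed, with 7 of 15 against 2.40 (Fisher's exact test, adjusted p = 0.044). Ribosomal and transfer RNA genes had 5 of 108 near a Nac site against 16.02 (Fisher's exact test, adjusted p = 0.0144), a call lost with gene ends within 150 bp (3 against 10.2, adjusted p = 0.121) or 500 bp (13 against 21.7, adjusted p = 0.191) and kept with genes near RpoD or RpoN sites as background (2 of 68 against 10.9, adjusted p = 0.0122). No pair passed for the other 8 lists, with the lowest adjusted p 0.434 for pyrimidines and nucleosides, 0.725 for polyamines, arginine and GABA, 0.0872 for amino acid biosynthesis, 0.174 for heat shock, 0.325 for flagella and chemotaxis, 0.464 for central carbon metabolism, 0.0872 for general stress and 0.0872 for ribosomal proteins. Within 500 bp general stress genes passed near RpoD sites, 23 of 24 against 16.7 (Fisher's exact test, adjusted p = 0.0312), as did nitrogen scavenging genes with fewer than expected, 27 of 53 against 36.9 (Fisher's exact test, adjusted p = 0.0358).

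RpoD at 354081 to 354131, beside codB, the cytosine transporter gene, had 28.8 under ammonia, 10.4 under glutamine, 50.8 under cytidine and 136.3 under cytosine. At 2511012 to 2511070, beside nupC, a nucleoside transporter gene, it had 3.90, 4.10, 9.09 and 15.4 in the same order. Nac was listed beside both genes under the 3 alternative sources, with 6.26, 10.7 and 6.13 at codB (354003 to 354066) and 37.7, 47.3 and 30.2 at nupC (2510914 to 2510947). Most RpoD sites beside pyrimidine and nucleoside genes were lower than under ammonia, at 18 of 20 sites under glutamine, 20 of 22 under cytidine and 19 of 22 under cytosine, with median log2 ratios of -1.02, -0.86 and -0.51, and 6, 5 and 8 of them lay above the RpoD median. The site beside codB is the strongest of the list for RpoD, and that beside nupC was chosen after its values were seen. RpoD at 3352514 to 3352565, beside gltB, of glutamate synthase, had 158 under ammonia and 9.56 under cytosine.

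Past the first stretch, 12.99% and 13.7% of RpoD centres lay outside coding sequences as numbered, close to the share of bases. RpoD sites lying mostly within genes is argued against by the first stretch, where 67.9% of centres lay outside coding sequences, against 14.2% of bases. The end of that stretch was itself fitted to the placement of these centres. A candidate explanation is that the files number the chromosome in fixed steps against the gene table. NtrC sites, not used to fit the steps, had 21 of 23 centres outside coding sequences at them, against 1 as numbered and at most 10 at other offsets. The count of nitrogen scavenging genes beside NtrC sites, 16 at the steps, 7 as numbered and between a median of 0 and a highest of 14 at 360 other offsets, did not decide it, and the 0.49 expected above is no guide to what a wrong offset can give. No other biological explanation was tested.

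Many sites are not listed under ammonia. A listing limit was tested by dividing the intensity of each missing site by the median ratio of the shared sites and counting those below the lowest listed ammonia intensity. For RpoN 7.35%, 12.3% and 10.96% lay below it (from glutamine, cytidine and cytosine). This cannot decide against a limit, as the ratio came only from sites listed under ammonia and the cutoff, 0.96, was the lowest of 312 values. The predicted medians of the missing sites, 1.67, 1.79 and 1.53, lay above that cutoff and below the lower quartile of listed ammonia values, 2.51. For Nac the shares were 97.8%, 85.8% and 66.7%, and for NtrC 83.3%, 88.9% and 88.9%. A limit and an absence of binding cannot be told apart for these 2 proteins either, as the share depends on the source or on 18 sites. Weaker binding under ammonia and a difference between base media stay open, untested.

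Some RpoN sites have the edges of Nac sites: 10 of the 19 RpoN sites within 100 bp of a Nac site had both edges within 5 bp. The other 9 did not, which leaves separate RpoN binding close to Nac sites open. Among the 9, however, the RpoN site at 1402594 to 1402639 lay inside the strongest Nac site, 1402593 to 1402659, and missed the rule only at its end. There RpoN was not listed under ammonia and had 0.49 under glutamine and 2.11 under cytosine, while Nac had 1558 and 113. DNA or reads of the Nac libraries in RpoN libraries is a candidate explanation. Of the 10 strongest Nac sites under cytosine, 5 had an RpoN site with both edges within 5 bp, against 5 of the other 520. A share that is the same for every source is argued against, since RpoN had between 3.04% and 4.41% of the Nac intensity at these 5 sites under cytosine, between 0.785% and 1.30% under cytidine, and at most 0.153% under glutamine, where 2 of the 5 were listed. Just below the 10 strongest, the sites at 3965686 and 4368487, ranked 11 and 17 under cytosine, had RpoN shares of 7.16% and 5.41% there. A share that differs between libraries stays open, and at 3 weak shared sites (2561401, 2563311 and 4010849) RpoN exceeded Nac under cytosine. None of the 5 among the 10 strongest was listed for RpoN under ammonia, and no other biological explanation was tested.

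A hypothesis is that cultures on the alternative sources held less zinc than those on ammonia, as some of the RpoD sites with the highest ratios lie, at the offsets, beside zinT (2039357), ykgM (312003) and znuA (1940607), genes of zinc uptake or sparing (the site at 2008573, beside yedL, does not). Less zinc in the cultures on the alternative sources would also lower RpoD beside zntA, a zinc exporter gene. Its site, at 3604433 to 3604484, lay below the median under 3 of 3 sources, which decides nothing: it is 1 site, the ratios share 1 ammonia value (0.84, below the RpoD lower quartile of 1.55), and 17.1%, 13.3% and 1.66% of RpoD sites had ratios as low. The ammonia values beside zinT and ykgM, 0.2 and 0.43, also lay below that quartile, and that beside znuA, 2.36, lay above it. A second hypothesis is that there was less of other metals as well, which may fit the iron uptake genes: the median log2 ratio of 15 sites beside iron uptake genes was 1.30, 1.06 and 1.45, against RpoD medians of -0.73, -0.45 and -0.21, at percentile 100 of 10000 random lists under each source, with the ammonia values shared by the 3 comparisons. It did not hold for every gene, as the site at 4516379 to 4516429, beside fecI, had log2 ratios of -1.04 and -0.77 under glutamine and cytidine. The base medium may differ with the source, so a nitrogen effect and a medium effect stay open.

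A further hypothesis is that large RpoD changes gather beside Nac sites. Under cytosine 12.4% of 178 RpoD sites near a Nac site lay at least 2 log2 units from the median, against 3.98% ± 2.27 (SD) over circular shifts of the Nac sites (permutation, adjusted p = 0.0096), with 16 sites above and 6 below. Under cytidine the share was 5.59% (8 above, 2 below; permutation, adjusted p = 0.162) and under glutamine 5.14% (9 above, 0 below; permutation, adjusted p = 0.393), so only 1 of 3 sources passed and the hypothesis was not decided. The shift test was run again with exact site widths after its first result was seen, and the same source passed both times.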
